A study of Danio rerio with 32 samples.

How the data were processed

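RNA of pooled whole zebrafish embryos was measured on 32 one-colour (Cy3) Agilent arrays, 16 per exposure time. Per the labels' protocols, RNA was taken with Trizol and RNeasy columns and labelled with the One-Color Quick Amp Labeling Kit. The deposited scanner files hold, per the file headers, the intensity of each spot as written by Agilent's Feature Extraction software. The processed intensity was already background-subtracted and detrended within each array by that software, per the file headers, and was not normalized between arrays. The files also give the mean pixel intensity of each spot and the median intensity of its local background. A value table deposited by the authors holds log2 values of the same arrays. Per the submitters' processing notes limma 3.16.5 was used for it, and the steps are not stated. Its column medians were 6.27 to 6.29 on 31 arrays and 6.58 on the remaining array, and its columns correlated with the log2 mean signal of their own array at 0.988 or more on the 31 arrays and at 0.771 on the remaining array. These values are therefore on a log2 scale with genes not centred. Its background correction stays unknown, and it was used as an alternative only.

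Each array held 61657 spots that were not controls. Spots the scanner software called outliers, 2 to 42 per array, were left out, and no spot was saturated. Spots of one probe were averaged, which gave 43603 probes. Of these, 28130 matched an accession of the RefSeq gene table (assembly GRCz12tu, used for names alone), and 29708 had an assigned gene symbol. Other probes keep the name the files give. Probe positions are those of the files, on the danRer7 (Zv9) build, 1-based. The files do not say whether a probe lies in an exon or a UTR. Signals were taken as log2 of the processed intensity minus each array's 75th percentile of it. A probe was kept where it was well above background on at least 2 arrays, which 37047 probes were. Each gene was represented by its probe with the highest mean signal, which left 22248 genes, 14100 of them with an assigned symbol. The number of arrays limits the precision, with 4 controls and 2 arrays per concentration at each time.

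Models were fitted with limma 3.58.1 in R 4.3.3 (data.table version 1.17.8, statmod 1.5.0), with lmFit and eBayes, and p values were adjusted over all genes by the Benjamini-Hochberg method, with 0.05 as the threshold. A single fit of all arrays gave a slope per exposure time over the steps 0 (control) to 6 (32 mg) of the doubling series, and the difference of the slopes. A second fit gave the difference of each concentration from the controls of its time, on which fold changes and their standard errors rest. Both carried batch within exposure time as a block, because the labels give the batch. Controls at 24 h and 12 h were compared with batch as a random block (duplicateCorrelation). The Carbo-Iron term was fitted beside the concentration groups. PCE arrays of the same batch deviated together from their group means, counted above a small positive r, at 12 h in all 30 array pairs (mean r 0.499, lowest 0.347). At 24 h they did so in 24 of 30 pairs (mean r 0.201, lowest -0.0701). Because each PCE group has an array in each of its batches, the pairs of the second batch repeat those of the first and add no evidence. Batch and Carbo-Iron cannot be told apart in this deviation. The fit with no replicate block called 171 genes for the 24 h trend.

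Gene lists, 32 in all with 8 to 79 measured members, covered toxicant and stress responses, metabolism, and the cell types of a whole embryo. They were fixed before the data were examined, as were the groups, the tests, the main design and the other settings to be tried. Lists were tested with limma's cameraPR at a preset correlation of 0.01 and again with an estimated correlation, with p values adjusted over the lists. Members were also counted with p values adjusted over all genes and adjusted over the list alone. Named genes follow a rule fixed at the same time. For a trend these are the 10 genes each way with the largest difference at 32 mg among those past the threshold, with the same sign in both batches, well above background on every array of the higher group, and with an assigned symbol. The rule takes 5 each way for the difference of trends, 10 for the controls, 3 for single concentrations, and the 4 members of each list with the smallest p. Where all arrays of a group were not well above background, the fold is a lower bound. For it the dimmer group's signals were raised, per array, to at least the lowest signal among probes well above background, and the smaller of the difference of group means and the fitted change was taken. Where the dimmer group's own signals already lay above that level, no fold is given.

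One control array at 24 h had very low signal and is called the dim array. The planned fit keeps it. A fit of 31 arrays without it is given beside most counts and most 24 h values. Leaving out each array in turn had been planned, but giving this one throughout was chosen after its signal had been seen. The 2 fits share the 12 h estimates, and they differ at 12 h in the spread, which is estimated over both times. Alternatives were normexp background correction (offset 50), quantile normalization, the authors' value table, no filter or a filter on all arrays, all probes, concentration on the linear scale, each time alone, each batch set alone, no replicate block, Carbo-Iron as a covariate, no Carbo-Iron control, eBayes with trend and robust, and each array left out. Linear concentrations and quantile normalization without the dim array, and 4 mg without a further array, were added after the data were seen. The genes whose single values were followed through the alternatives make 177 named results. This scope was narrowed after reversals had been seen. It leaves out 48 list members and 23 genes of single concentrations that the rule names in the fit without the dim array alone, and the dependence of these is given as counts.

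The fits were tested on simulated data with known changes. The simulated arrays took their spread from the fit without the dim array, and no dim array was among them. The shares below therefore do not describe the planned fit, which holds that array. Simulated noise was drawn in a single run and independently for each gene. The shares therefore do not cover variation that genes share within an array. For the 24 h trend, 57% of genes changed by 1 (log2 at 32 mg) and 93% of genes changed by 2 were recovered, with 8% of calls outside the changed genes. For 32 mg at 24 h the shares were 39% and 86%, and for the difference of trends 34% and 78%. For the controls 75.5% of genes changed by 2 were recovered. No gene was called in the simulated 12 h trend, in which none had been changed. Chance was tested by refitting the trends with concentrations reassigned within batch, 100 assignments in all, and the control comparison over the 3 splits of the controls that keep batches whole.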

Results

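Gene expression was measured in pooled whole zebrafish embryos (Danio rerio) after 12 h or 24 h of exposure to PCE. The labels do not spell the abbreviation out. It commonly stands for perchloroethylene (tetrachloroethene), a chlorinated solvent. The 6 concentrations are labelled 1, 2, 4, 8, 16 and 32 mg, with no volume given. At each exposure time there were 4 control arrays and 2 arrays per concentration, which the series design calls biological replicates. The arrays fell into 4 batches, each also 1 slide and 1 scan, with 2 controls and every concentration once in each. Batches 3 and 4 held the 12 h arrays, and batches 5 and 6 the 24 h arrays. In batches 4 and 6 the embryos of 7 of the 8 arrays, 1 of the controls among them, also received 10 mg/l Carbo-Iron, a nanomaterial of iron on activated carbon that the design text describes as without effect on gene expression.

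Array brightness was similar on 31 of the 32 arrays. Their 75th percentile of processed signal lay between 280 and 840, and 60.11% to 79.7% of their spots were well above background. In 1 control at 24 h (replicate 5-K1 of batch 5), the dim array, the percentile was 5.27 and 17.9% of spots were well above background. Its median correlation with the other arrays across probes was 0.478, against 0.963 to 0.977 on the rest. Mean 75th percentiles (± SD) were 481 ± 129 in batch 3, 712 ± 114 in batch 4, 583 ± 49.5 over the other 7 arrays of batch 5, and 457 ± 106 in batch 6. With all 32 arrays, the median difference of all genes from the 24 h controls was -0.25 to -0.33 (log2) at the 6 concentrations, and without the dim array it was -0.02 to 0.03. Most values at 24 h are therefore given from both fits.

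**Figure D1:**
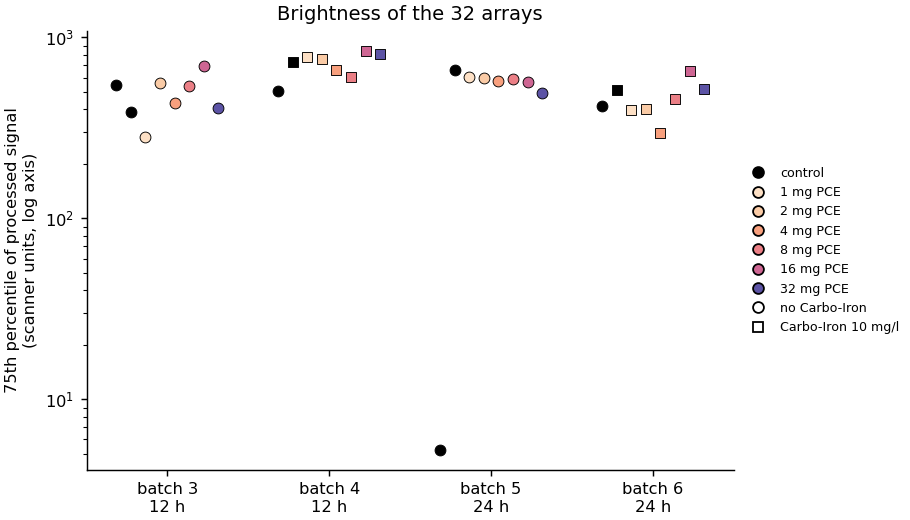
Brightness of the 32 arrays by batch, as the 75th percentile of processed signal (log axis). The dim array (5.27) lies far below the other 31, which span 280 to 840.

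At 12 h the question was which genes followed the concentration of PCE. With all 32 arrays 24 genes had a concentration trend, 21 rising and 3 falling. Among the genes that the naming rule takes, the rise at 32 mg was largest in ethe1, which encodes the mitochondrial sulfur dioxygenase of hydrogen sulfide oxidation (probe on chromosome 16, 57840646 to 57840813). It was 6.05-fold higher than in the controls (log2 change 2.60 ± 0.24, SE, n = 2 and 4 arrays, adjusted p of the slope 0.000986), with 2.48 and 2.71 within batches 3 and 4. The short-chain dehydrogenase gene dhrs13l1 was 5.82-fold higher (2.54 ± 0.34), and the thiopurine methyltransferase genes tpmt.1 and tpmt.2 were 4.42-fold (2.15 ± 0.31) and 4.34-fold (2.12 ± 0.33) higher. The stathmin gene stmn4l rose 3.85-fold (1.95 ± 0.34), the Ras-related rasd1 3.63-fold, the glutathione reductase gene gsr 3.14-fold (1.65 ± 0.29), the pirin gene pir 3.01-fold, the oxidoreductase gene htatip2 2.82-fold and the glucuronosyltransferase gene ugt1a7 2.65-fold. The 3 genes that fell were dhrs11b.2, another short-chain dehydrogenase (2.37-fold lower, -1.24 ± 0.29), the skeletal actin gene acta1b (2.34-fold lower, -1.23 ± 0.28) and the keratin gene krt91 (2.15-fold lower, -1.10 ± 0.26). All 13 of these slopes passed limma's test with adjusted p between 0.000986 and 0.0394. With all 32 arrays the difference at 32 mg itself did not pass limma's comparison with the controls for htatip2 (adjusted p 0.446). Nor did it for dhrs11b.2 (0.199), acta1b (0.139) and krt91 (0.194). Without the dim array, which leaves the 12 h estimates as they were and narrows the shared spread, 183 genes passed, 124 rising and 59 falling.

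Among the genes that passed at 12 h only without the dim array were bbc3, which encodes a proapoptotic protein (6.94-fold higher at 32 mg, 2.80 ± 0.32, adjusted p of the slope 0.0224), the follistatin gene fsta (4.58-fold), the stress transcription factor gene ddit3 (3.95-fold, 1.98 ± 0.45), the sulfotransferase gene sult1st5 (4.29-fold, 2 of 4 controls above background) and the kinase gene wnk4b (4.05-fold, 3 of 4 controls above background). The prostaglandin reductase gene ptgr1.2 was at least 7.69-fold higher, with no control above background. Falls were found in 4 calreticulin genes, which encode calcium-binding chaperones of the endoplasmic reticulum. They were calr3b (3.40-fold, -1.76 ± 0.30), calr (2.69-fold, -1.43 ± 0.23), calr3a (2.35-fold, -1.23 ± 0.15) and calrl (2.29-fold). The transgelin gene tagln (2.52-fold), jac6 (2.69-fold), the cholesterol transporter gene abca1a (-1.27 ± 0.21) and the immunoproteasome gene psmb9a (3.46-fold, 1 of the 2 arrays at 32 mg above background) also had falling slopes. At 32 mg itself jac6 (adjusted p 0.0532) and psmb9a (0.0991) did not pass limma's comparison in this fit.

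The list of p53 target genes moved up at 12 h. Of its 27 measured members 1 rose and 0 fell over all genes tested, 7 passed when adjusted over the list alone, and without the dim array 5 rose, with 13 past the threshold adjusted over the list alone. Their median change at 32 mg was 0.62 (0.44 in batch 3 and 0.76 in batch 4), with adjusted p = 2.16e-18 at the preset correlation and adjusted p = 0.00255 with an estimated correlation. The DNA repair gene ddb2 rose (0.85 ± 0.25, adjusted p of the slope 0.0376), and without the dim array so did the growth arrest genes gadd45aa (1.72 ± 0.28) and gadd45ga (2.83-fold). No other list held at 12 h with an estimated correlation in either fit.

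Of the 35 Nrf2 antioxidant genes 2 rose and 0 fell, gsr and osgn1 (1.16 ± 0.23), 5 passed adjusted over the list alone, and 4 rose without the dim array, prdx1 (1.12 ± 0.22) and gstp1.2 (1.68 ± 0.23) being added. The list's adjusted p was 0.00105 at the preset correlation and adjusted p = 0.22 with an estimated correlation. The unfolded protein and integrated stress response list (40 members) moved down with a median at 32 mg of -0.22 (adjusted p = 0.00151, adjusted p = 0.179 under normexp, and adjusted p = 0.417 with an estimated correlation). None of its members passed over all genes and 8 did adjusted over the list alone. Without the dim array 8 fell, calr, calr3a and calr3b among them, and 3 rose, namely ddit3, the stress sensor gene sesn2 (1.65 ± 0.31) and chac1, which encodes a glutathione-degrading enzyme (1.14 ± 0.33). Ribosomal proteins (76 members, median -0.35, adjusted p = 6.8e-26) and oxidative phosphorylation (79 members, median -0.27, adjusted p = 3.84e-08) moved down with no single member past the threshold. Their adjusted p with an estimated correlation was 0.109 and 0.464, and at the preset correlation the ribosomal list did not pass under quantile normalization (adjusted p = 0.158) or with the authors' value table (adjusted p = 0.091). In total 14 lists passed at the preset correlation at 12 h, 6 up and 8 down, and 13 without the dim array. This balance turned with the scaling, with 10 up and 3 down under normexp, 9 and 4 under quantile normalization, 10 and 4 with the authors' value table, and 10 and 5 in batches 4 and 6 alone. The iron and metal handling list did not pass with all 32 arrays (adjusted p = 0.0752), and passed as moving up without the dim array (adjusted p = 0.00447), under normexp (adjusted p = 0.00576), under quantile normalization (adjusted p = 0.00151) and with that table (adjusted p = 0.000382), but not with an estimated correlation (adjusted p = 0.0896, and adjusted p = 0.18 without the dim array).

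At 24 h 304 genes had a concentration trend with all 32 arrays, 122 rising and 182 falling, and 1231 without the dim array, 565 rising and 666 falling. The ubiquitin-like interferon-induced gene isg15 (chromosome 5, 21896031 to 21896090) was 13.7-fold higher at 32 mg (3.78 ± 0.95, adjusted p of the slope 0.0395), and 27.7-fold without the dim array (4.79 ± 0.70, adjusted p 0.00067), with 2 of the 4 controls above background. The glutathione transferase gene gstp1.2 was 7.38-fold higher (2.88 ± 0.61), and 4.16-fold without the dim array (2.06 ± 0.25). The stathmin gene stmn4l was 6.13-fold higher (2.62 ± 0.34, adjusted p 0.000152), and 5.69-fold without the dim array. The arginase gene arg2 was 5.07-fold higher (2.34 ± 0.28, adjusted p 6.84e-06) and 4.66-fold without the dim array. The stress sensor gene sesn2 was 4.86-fold (2.28 ± 0.33) and the cone transducin gene gnat2 4.80-fold higher (2.26 ± 0.29), with 5.07-fold and 5.65-fold in the second fit. Rises with all arrays, and in parentheses without the dim array, were also found for the matrix protease gene mmp9, 6.18-fold (5.44-fold), the fibronectin gene fn1b, 6.09-fold (4.15-fold), the growth factor binding protein gene igfbp1a, 6.04-fold (5.13-fold), and the cathepsin gene ctsla, 4.95-fold (3.05-fold). For most of these genes 3 of the 4 controls were above background, the dim array being the exception. With all arrays the difference of isg15 at 32 mg did not itself pass limma's comparison (adjusted p 0.0752). Without the dim array it did (adjusted p 0.00037).

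For falling genes the naming rule asks for signal well above background on every control, the dim array included, and 13 genes met it with all 32 arrays. Outside the rule, col10a1a had the smallest p of limma's comparison at 32 mg and 24 h with all 32 arrays (adjusted p 0.000125). Among the genes that fell at 24 h, otx5, a homeobox gene of the retina and pineal organ, was 4.29-fold lower at 32 mg (-2.10 ± 0.31) and 3.56-fold lower without the dim array. The actinodin gene and4, which encodes a structural protein of the fin fold, was 4.19-fold lower (-2.07 ± 0.34) and 3.29-fold lower without the dim array. The retinol-binding protein gene rbp4 was 2.09-fold lower (-1.06 ± 0.23), and 2.38-fold without the dim array (-1.25 ± 0.17). The keratin gene krt91 was lower (-1.14 ± 0.26, -1.02 ± 0.23 without the dim array), and krt94 was 2.02-fold lower and 2.59-fold without the dim array. The vasopressin gene avp was 2.82-fold lower and 1.96-fold without the dim array. Lower values were also found for echdc1 (3.05-fold, 1.80-fold without the dim array), ptrhd1 (2.75-fold, 2.23-fold), the oligosaccharyltransferase gene ost4 (2.13-fold, 2.12-fold) and hdhd2 (1.96-fold, 1.53-fold). With all 32 arrays the slopes of these genes passed. The difference at 32 mg itself did not pass limma's comparison for krt94 (adjusted p 0.272), avp (0.191), echdc1 (0.257), ost4 (0.141) and hdhd2 (0.27). Large falls in the fit without the dim array were found in the small heat shock protein gene hspb9 (chromosome 3, 33438132 to 33438190, 39.5-fold, -5.30 ± 0.51, adjusted p 3.59e-05), ponzr3 (27.7-fold, 1 of 2 arrays at 32 mg above background). The cartilage collagen gene col10a1a (chromosome 17, 15383404 to 15383463, adjusted p 0.00067) and the recoverin gene rcvrna (adjusted p 0.00396) also had falling slopes in that fit, where no array at 32 mg was above background and no bound could be set. Falls were also found in the rhodopsin gene rho (9.63-fold, -3.27 ± 0.61, with -1.66 and -4.66 in batches 5 and 6), the sterol hydroxylase gene cyp8b1.1 (at least 5.78-fold), tmx3a (8.08-fold), lgals3bp.1 (at least 6.61-fold) and nherf4b (at least 5.11-fold). Besides isg15, large rises in that fit were found in the Polycomb gene cbx7a (19.7-fold, 4.30 ± 0.45, adjusted p 0.0171), the pim-related kinase genes pimr213 (14.7-fold) and pimr110 (13.1-fold), the tryptophan hydroxylase gene tph1a (at least 9.70-fold), the presomitic mesoderm gene msgn1 (9.68-fold), ptgr1.2 (9.26-fold) and gipc3 (8.56-fold). Rising slopes were also found for pimr128 (adjusted p 0.0199) and prss60.1 (adjusted p 0.00141), where no control was above background and no bound could be set. None of these 9 genes passed with all 32 arrays. The slopes of tph1a, gipc3 and the 3 pim-related genes changed sign under 1 or more other settings.

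**Figure D2:**
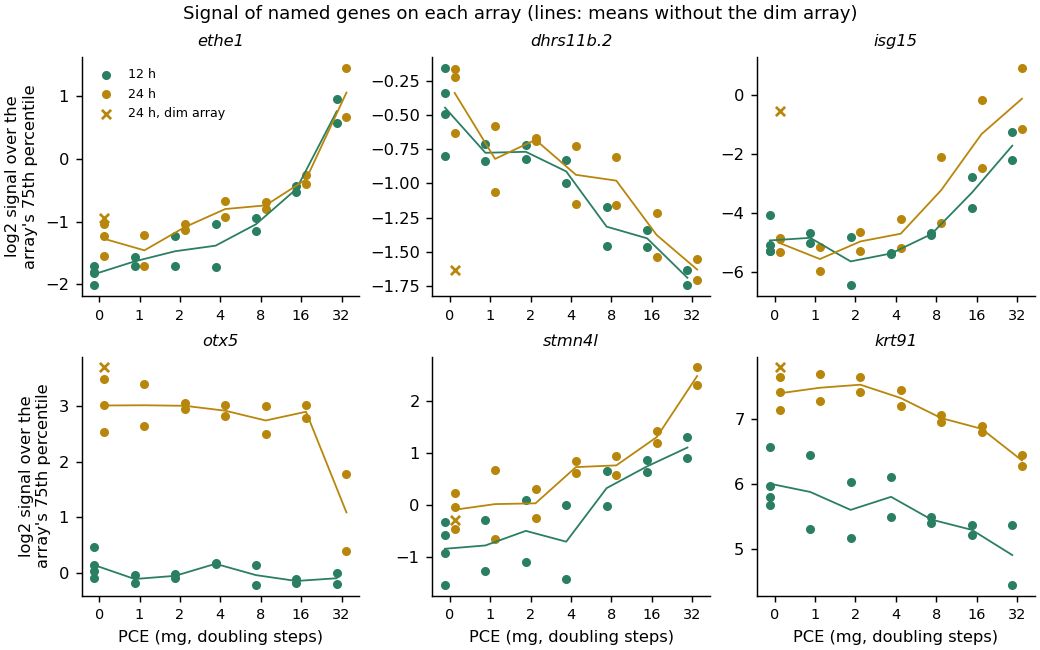
Log2 signal relative to the 75th percentile of the array against PCE concentration for ethe1, dhrs11b.2, isg15, otx5, stmn4l and krt91, with a point per array at 12 h and 24 h, lines through the means without the dim array, and a cross for the dim array. At 32 mg ethe1 stood 2.60 above the 12 h controls and isg15 stood 4.79 above the 24 h controls without the dim array.

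Grouped by list at 24 h, photoreceptor genes moved down in both fits at the preset correlation, and did not pass with an estimated one (adjusted p = 0.34, and adjusted p = 0.411 without the dim array). Of 50 members 8 fell and 2 rose, 20 passed adjusted over the list alone, and the median at 32 mg was -1.16 (-1.92 in batch 5, which holds the dim array, and -0.66 in batch 6). In the fit without the dim array 12 fell and 3 rose, with a median of -0.45 (-0.22 and -0.66). Examples of falls were rho, rcvrna, the transducin gene gnb3a (-2.23 ± 0.42, -1.91 ± 0.36 without the dim array) and the melatonin synthesis gene aanat2 (4.13-fold lower, 2.47-fold without the dim array), while gnat2 rose. The lens list (58 members) likewise moved down at the preset correlation, with a median of -0.65 (-0.79 without the dim array), and not with an estimated one (adjusted p = 0.513 and adjusted p = 0.411). Of its members 2 fell (5 without the dim array), the crystallin genes crybb2 (at least 5.93-fold, at least 3.48-fold) and crybb1l3 (-1.61 ± 0.34, -1.42 ± 0.31) in both fits. The adjusted p of the photoreceptor list was 5.96e-07 and that of the lens list 0.000439 at the preset correlation. Both passed as moving down under quantile normalization and with the authors' value table too, and under normexp the photoreceptor list passed (adjusted p = 0.000202) and the lens list did not (adjusted p = 0.549).

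The p53 target genes moved up at 24 h as well, with 2 risen (4 without the dim array), 8 past the threshold adjusted over the list alone, and a median of 0.81 at 32 mg (0.51 without the dim array, 0.67 and 0.46 within batches 5 and 6). The growth arrest gene gadd45ab (1.68 ± 0.32, 1.49 ± 0.29 without the dim array) and the survival gene mcl1a (1.59 ± 0.41, 1.15 ± 0.27) rose in both fits. Of the Nrf2 antioxidant genes 3 rose, gsr (2.00 ± 0.29, 1.69 ± 0.18), gstp1.2 and the autophagy receptor gene sqstm1 (1.59 ± 0.40, 1.24 ± 0.31), and none fell. In the iron and metal handling list (30 members) the ferritin genes fthl28 (3.44-fold, 2.64-fold without the dim array) and fthl29 (1.88 ± 0.54, 1.15 ± 0.18) rose, and the hepcidin gene hamp fell (-2.83 ± 0.68, -2.25 ± 0.58). With an estimated correlation the adjusted p with all 32 arrays was 0.0235 for p53 targets, 0.0377 for Nrf2 genes and 0.0153 for iron handling, and without the dim array it was 0.353, 0.411 and 0.353, so that no list held in that fit. The hypoxia list (41 members) also passed with all arrays (adjusted p = 0.0377 with an estimated correlation), moving up relative to other genes although its median slope was -0.01, with 1 gene risen, igfbp1a, and without the dim array adjusted p = 0.82 with an estimated correlation. At the preset correlation the hypoxia list did not pass with the authors' value table (adjusted p = 0.112), nor iron handling under quantile normalization (adjusted p = 0.0566).

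Further lists passed at the preset correlation and not with an estimated one. The cholesterol synthesis list moved up in both fits (29 members, 2 risen with all arrays, 5 without the dim array, adjusted p = 0.513 and 0.411 with an estimated correlation, and a mean slope of -0.01 against a median of 0.03 with all arrays), with hmgcra, the rate-limiting reductase gene (1.18 ± 0.32 in both fits), and mvda (0.86 ± 0.20, 0.77 ± 0.16). Under normexp the cholesterol list did not pass (adjusted p = 0.107, median slope -0.02). Moving up as well was inflammation and acute phase (64 members, 4 risen and 1 fallen, adjusted p = 0.34 with an estimated correlation), with isg15, mmp9 and the cytokine suppressor gene socs3b (2.19 ± 0.40) risen and hamp fallen. Leaving out the dim array turned the direction of several lists. Oxidative phosphorylation, the unfolded protein list and skeletal muscle (64 members) passed as moving up with all 32 arrays and as moving down without it. Cell cycle and DNA replication (73 members) and fatty acid oxidation and PPAR targets (56) passed as moving up with all 32 arrays alone, and ribosomal proteins passed as moving down without the dim array alone. With all 32 arrays the calls of oxidative phosphorylation and the unfolded protein list ended under quantile normalization (adjusted p = 0.404 and 0.193) and with the authors' value table (adjusted p = 0.292 and 0.104), while ribosomal proteins passed as moving up under normexp (adjusted p = 1.88e-16) and with that table (adjusted p = 0.0266). Under quantile normalization without the dim array the unfolded protein list, skeletal muscle and ribosomal proteins did not pass (adjusted p = 0.234, 0.685 and 0.34), and the cell cycle list passed as moving up (adjusted p = 0.0354). Of the 79 oxidative phosphorylation genes 13 fell without the dim array, cox4i1 (-0.72 ± 0.18) and ndufb9 (-0.75 ± 0.25) among them, and of the unfolded protein list 9 fell and 2 rose, calr again among the first (-1.42 ± 0.24) and sesn2 and chac1 the second. Their adjusted p with an estimated correlation was 0.411 and 0.516. In total 14 lists passed at the preset correlation, 12 up and 2 down, and without the dim array 14 passed, 5 up and 9 down. With all arrays it was 17 up and 3 down under normexp, 9 and 2 under quantile normalization, and 11 and 2 with the authors' value table, but 1 up and 7 down in batches 4 and 6 alone. Under quantile normalization without the dim array it was 7 up and 6 down.

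**Figure D3:**
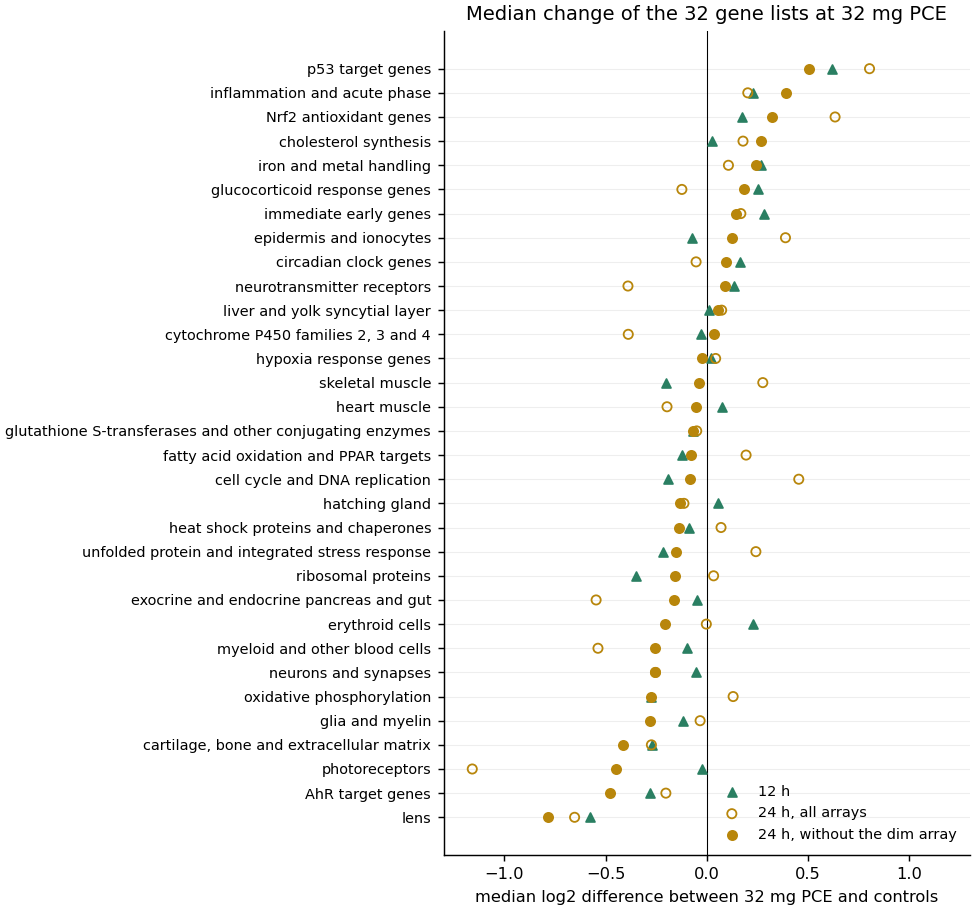
Median log2 change at 32 mg of the members of each of the 32 gene lists, as triangles for 12 h, open circles for 24 h with all arrays and filled circles for 24 h without the dim array. The p53 target genes lay at 0.62 at 12 h, and at 24 h the photoreceptor genes lay at -1.16 with all arrays and -0.45 without the dim array.

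Single concentrations were compared with the controls of their time. At 32 mg and 12 h 32 genes differed with all arrays, 30 higher and 2 lower, and 303 without the dim array (228 higher and 75 lower). The 2 lower genes were the actinodin gene and3 (-2.38 ± 0.31) and an unnamed transcript, ENSDART00000111141 (-1.77 ± 0.29), named here after their values were seen. At 32 mg and 24 h 193 genes differed, 91 higher and 102 lower, and 1901 without the dim array (1116 and 785). At 16 mg and 24 h 4 genes differed, of which arg2 was higher (1.71 ± 0.28, adjusted p 0.0479). The 3 lower genes, named after their values were seen, were hspb9 (-6.59 ± 0.79), the muscle gene pdlim3b (-1.85 ± 0.27) and ENSDART00000111141 (-1.74 ± 0.29). There were 21 such genes without the dim array. With all 32 arrays limma called no gene at 16 mg and 12 h (229 genes at an unadjusted p under 0.05), 8 mg and 24 h (1177) or 4 mg and 24 h (2002), and without the dim array it called 18, 19 and 222. In that fit the 222 genes at 4 mg and 24 h exceeded the 19 at 8 mg and the 21 at 16 mg. The 24 h counts thus did not rise steadily with concentration. At 2 mg and 12 h it called none (71 unadjusted) and 1 without the dim array, the unnamed probe A_15_P706186 (3.44 ± 0.27), named after its value was seen. No gene was called in either fit at 1 mg and 12 h (23 at an unadjusted p under 0.05 with all arrays, 510 without the dim array), 4 mg and 12 h (169, 1473), 8 mg and 12 h (261, 1963), 1 mg and 24 h (1434, 974) or 2 mg and 24 h (1353, 1086).

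**Figure D4:**
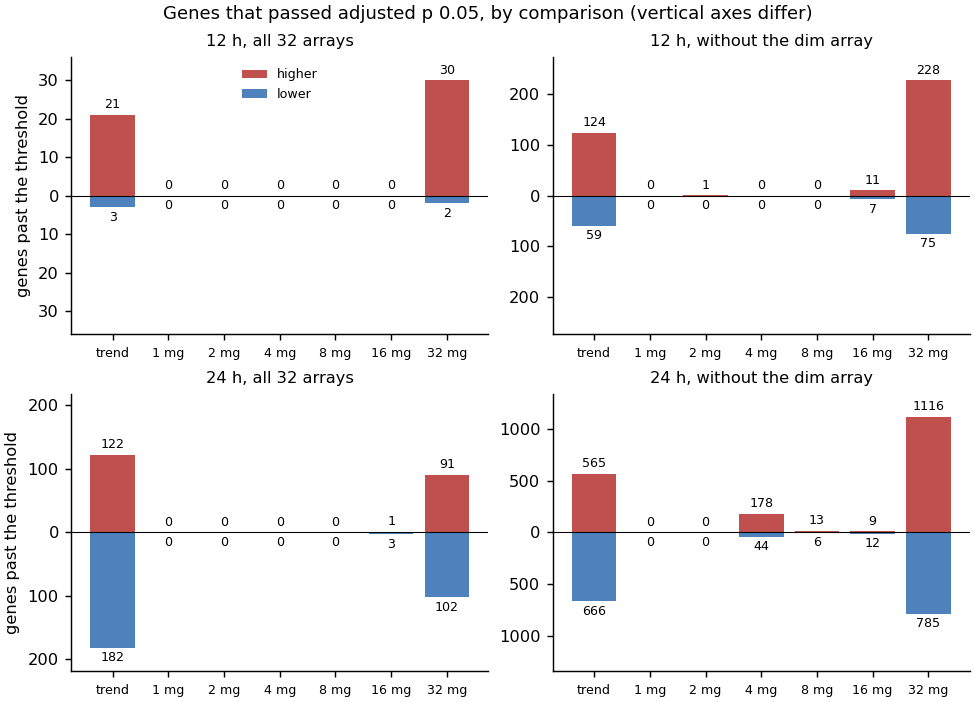
Number of genes past the threshold in each comparison, split into higher and lower, with all 32 arrays and without the dim array. The 24 h trend had 304 genes with all arrays and 1231 without the dim array.

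The trends of both times were compared directly. With all 32 arrays limma called no gene with a different slope at 24 h and 12 h (989 at an unadjusted p under 0.05). Leaving out the dim array gave 4 genes, all with a lower slope at 24 h. They were myog, a myogenic transcription factor gene (difference -0.28 ± 0.05 per step, adjusted p 0.04), the glucose transporter gene slc2a2 (-0.21 ± 0.04), the muscle gene xirp1 (-0.21 ± 0.04) and, named after its value was seen, cyp8b1.1 (-0.43 ± 0.08). With each time fitted alone and all arrays, 123 genes rose at 12 h and 5 at 24 h, and all 5 were shared, against 0.0276 expected of independent lists. They were stmn4l, arg2, gsr, rabgap1l2 and LOC100005016. Of 42 and 9 falling genes 0 were shared. Of 123 and 84 rising genes 28 were shared without the dim array, and of 42 and 147 falling genes 15 were (0.464 and 0.278 expected), and no gene was called in opposite directions. The 2 times have separate controls.

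Controls at 24 h and 12 h were compared as a measure of development between the sampling times. With all arrays 14 genes differed, 13 higher and 1 lower at 24 h, and without the dim array 291 (242 higher and 49 lower). The retinal transcription factor genes six7 (6.64 ± 0.49, adjusted p 0.013) and crx (5.07 ± 0.56) and the lens crystallin gene cryaa (3.49 ± 0.42) were higher, and the cathepsin gene ctss2.1 (-4.27 ± 0.51) was lower. The higher genes without the dim array also included ampd1 of muscle purine metabolism (adjusted p 0.000478), the photoreceptor genes nr2e3 (4.90) and samd7 (4.86), and foxq2, the lens gene lgsn and col10a1a, which no 12 h control had above background, and the lower genes included the left-right signalling genes lft2 (-3.37) and lft1 (-2.32), tnnt2c (-2.65) and cyp4t8 (-2.62).

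Carbo-Iron, fitted as a term across both times, gave no gene with limma in either fit (346 genes at an unadjusted p under 0.05 with all arrays, 1300 without the dim array). Of the 14 Carbo-Iron arrays all lie in batches 4 and 6, so that with batch as a block the term rests on the controls 4-K1 and 6-K1, which received none. Slopes fitted within each batch correlated across 22200 genes at 0.338 between batches 3 and 4 (12 h). Between batches 5 and 6 (24 h) they correlated at -0.0607 with the dim array and at 0.299 without it. Genes are not independent replicates, so these values carry no test. Between batches of different times the mean was 0.169, and 0.302 without the dim array.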

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

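Tests without the dim array, the splits of controls into whole batches, and the naming of cyp8b1.1 were chosen only after the signals or results had been seen, while the other tests of this part were planned. The control 5-K1 at 24 h stood far from the other 3 controls of its time in 3 measures. Its gap to the nearest control made up 0.906 of the controls' range in the log2 75th percentile of signal, 0.831 in the percent of spots well above background and 0.993 in the median of the authors' value table, each above Dixon's 95% critical value for 4 samples. Of 100 genes examined for such a control, 5 had one at 12 h and 24 at 24 h. These were the genes named by the rule, many of them only in the fit without the dim array. They were thus picked from the same data, and their share at 24 h cannot be set against a chance rate. No biological explanation was tested, since the 4 controls of a time form 1 group.

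Chance was examined by reassigning concentrations within batch. For the 12 h trend only the real assignment (1 of 100) gave as many genes (24, highest other 0), and likewise without the dim array (1 of 100, 183 genes, highest other 1). For the 24 h trend 4 of 100 assignments gave as many genes as the real one (304), and the highest other gave 5422, several times the real count, which points to a structure of the samples. In the fit without the dim array only the real assignment did (1 of 100, 1231 genes, highest other 39), so the dim array is a candidate source of that structure. Chance is excluded at the share of 0.05 for both 12 h counts and for the 24 h count without the dim array. The 24 h count with all arrays met that share narrowly, with 4 of 100. Because another assignment gave several times as many genes, chance stays open for that count. For 24 h against 12 h controls the exposure time varies between batches alone, so the bound first set over all splits of the controls, most of which break up batches, was dropped after its outcome had been seen. Only 3 splits keep batches whole, too few for a share under 0.05 (1 of 3, 14 genes, highest other 0, and without the dim array 291 genes, highest other 0).

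Differences between the exposure times were tested by the difference of slopes, and all of the following came from the fit without the dim array. The slope of the myogenic gene myog was lower at 24 h by -0.278 per step (change at 32 mg 0.85 ± 0.25 at 12 h and -1.17 ± 0.27 at 24 h). In the planned fit its 24 h slope was -0.115. Over 47 other settings that slope ranged from -0.252 to 0.0493 and changed sign in 3. The slope of the glucose transporter gene slc2a2 differed by -0.211 and that of the muscle gene xirp1 by -0.206. The median difference of slopes of the erythroid list was -0.0589 (adjusted p = 0.0395 with an estimated correlation). With all 32 arrays limma called none of the 3 genes in this comparison (989 genes at an unadjusted p under 0.05). The erythroid list did not pass there (adjusted p = 0.323 at the preset correlation), 11 other lists did at that correlation, and none did with an estimated one.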

How the results depend on the processing

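Linear concentrations and quantile normalization without the dim array, and 4 mg at 24 h without a further array, were chosen after the data had been seen, and the other settings were planned. Counts are genes past the threshold, with the planned fit's value first. The scope of the single genes followed here was narrowed after reversals had been seen. Of the 48 list members left out 28 reversed in at least 1 setting, and of the 23 genes of single concentrations left out 4 did. The cause of the changes below was not tested, also where fewer arrays, genes or batches make the fit smaller.

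The 12 h trend (24 genes) had 14 under normexp, 10 under quantile normalization, 15 with the authors' value table, 4 with probes well above background on all 32 arrays, 0 in batches 3 and 5 alone, 67 on the linear scale and 165 with the time fitted alone. The 24 h trend (304) had 122 under normexp, 16 with the filter on all arrays, 1 in batches 3 and 5, 150 in batches 4 and 6, 14 with the time fitted alone, 171 with no replicate block and 604 without the Carbo-Iron control of each time. In batches 4 and 6 alone the 12 h trend had 28 genes. Batches 3 and 5 hold the dim array and no Carbo-Iron, and every PCE array of batches 4 and 6 had Carbo-Iron. The batch sets therefore do not tell Carbo-Iron, the dim array and batch apart. The difference of trends (0) had 1 in batches 4 and 6 and 10 on the linear scale. At 32 mg and 12 h (32) there were 15 under normexp, 9 under quantile normalization, 13 with the authors' table, 1 with the filter on all arrays, 0 in batches 3 and 5 as in batches 4 and 6, 407 with the time alone and 15 without the Carbo-Iron control. At 32 mg and 24 h (193) there were 80 under normexp, 12 with the filter on all arrays, 0 in either batch set alone, 7 with the time alone and 98 with no replicate block. At 16 mg and 24 h (4) there were 2 under normexp, with all probes, with no filter and with Carbo-Iron as a covariate, 1 with no replicate block, and 0 with the authors' table, the filter on all arrays, batches 3 and 5 alone and the time alone. The counts of 0 became, at 2 mg and 12 h, 1 under quantile normalization and with the time alone, at 8 mg and 12 h, 21 in batches 4 and 6 and 1 with the time alone, at 16 mg and 12 h, 4 with the time alone and 1 with all probes as with trend and robust eBayes, at 8 mg and 24 h, 7 under quantile normalization, 6 with the authors' table and 14 in batches 4 and 6, and without the Carbo-Iron control 1, 3 and 2 at 1, 2 and 4 mg and 24 h. The controls (14) had 1 under normexp, 5 under quantile normalization, 7 with the authors' table, 3 with the filter on all arrays, 9 with all probes, 8 with no filter, 28 with trend and robust eBayes, 35 with batch not a random block and 4193 without the Carbo-Iron control. Lists past the preset correlation at 24 h (14) were 6 with the filter on all arrays and 8 in batches 4 and 6, and for the difference of trends (11) 7 under quantile normalization, with the filter on all arrays and in batches 4 and 6. With no replicate block the 12 h trend had 16 genes and 32 mg at 12 h had 23. Correlations of slopes between batches were 0.53 at 12 h and 0.166 at 24 h on the linear scale, and -0.385 at 24 h with the filter on all arrays.

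The linear scale without the dim array gave 379 genes at 12 h, 2981 at 24 h and 30 for the difference, with batch correlations of 0.53, 0.394 and, across times, 0.461. Quantile normalization without the dim array gave 262, 1264 and 7 for these, 1, 12, 27 and 396 at 2, 8, 16 and 32 mg and 12 h, 1, 1, 224, 26, 31 and 2013 at 1, 2, 4, 8, 16 and 32 mg and 24 h, 423 for the controls and a 24 h batch correlation of 0.312. At 4 mg and 24 h there were 221 genes without the batch 5 array of 4 mg too. The rising genes of the 24 h trend were 122 of 304, but 126 of 213 under quantile normalization and 63.3% with the authors' table. The share of higher genes at 32 mg and 24 h was 47.2%, but 59.7% and 63.3%, that in the 12 h trend 87.5%, but 73.3% with the authors' table, and that at 32 mg and 12 h 93.8%, but 77.8% under quantile normalization.

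Slopes reversed for gabra3 at 12 h under normexp (-0.00317). At 24 h they reversed for mvda with the filter on all arrays (-0.102), cyp2p9 under quantile normalization (0.0131) and with the authors' table (0.0014), bag2 with the authors' table (0.0391), cox4i1 (0.0336) and fabp7a (0.00308) under normexp, tph1a under normexp (-0.0463) and in batches 3 and 5 (-0.00437), pimr128 with all probes (-0.257) and in batches 3 and 5 (-0.0613), pimr213 in batches 3 and 5 (-0.0851), pimr110 under normexp (-0.00691), with the authors' table (-0.0419) and in batches 3 and 5 (-0.0255), and gipc3 under normexp (-0.0562), with the authors' table (-0.104), with all probes (-0.0922), in batches 3 and 5 (-0.33), without the Carbo-Iron control (-0.0157) and with single arrays left out (slopes of -0.0684 to 0.362, below 0 without 5-K2, 6-K1, 6-K2 or either array of 32 mg).

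With each array left out in turn the ranges were 9 to 183 (12 h trend), 36 to 1231 (24 h trend), 0 to 4 (difference), 0 to 1 at 2 mg, 0 to 14 at 4 mg, 0 to 18 at 16 mg and 1 to 303 at 32 mg and 12 h, 0 to 0 at 1 and 8 mg and 12 h, 0 to 1, 0 to 3, 0 to 222, 0 to 19, 0 to 21 and 15 to 1901 from 1 to 32 mg and 24 h, 0 to 7 (Carbo-Iron, the highest without 4-K1), 0 to 291 (controls), 9 to 17, 10 to 16 and 4 to 13 lists for 12 h, 24 h and the difference, and batch correlations of 0.149 to 0.379, -0.147 to 0.299 and 0.0953 to 0.302. Where 1 array remained in a group, it is assumed to vary like the others. The highest counts mostly came without the dim array, and the lowest without an array at 32 mg, which left 10 and 9 genes at 12 h (batches 3 and 4), and 36 and 47 at 24 h (batches 5 and 6). At 24 h the count also rose to 496 without the 1 mg array of batch 5 and 696 without 6-K2. At 32 mg it became 1 without either 12 h array, 14 without 4-K1, 21 without 4-K2, and at 24 h 15 and 94 without its own arrays and 358 without 6-K2. The controls fell to 0 without 3-K1, 4-K1, 4-K2 or 5-K2 and to 3 without 3-K2, and rose to 172 and 154 without 6-K1 and 6-K2. Signal over background limits the dim array most, where 17.9% of spots were well above background.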

Other observations

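Several further gene groups held changed members at 24 h. Among AhR target genes (11 members) 2 fell and none rose, cyp1c1, a cytochrome P450 of family 1 (-1.88 ± 0.32, -1.90 ± 0.32 without the dim array), and foxq1a (-2.74 ± 0.43, -2.47 ± 0.40). At the preset correlation the list passed as moving down at 12 h with all arrays (adjusted p = 0.0144) and not without the dim array (adjusted p = 0.0684), and at 24 h without the dim array (adjusted p = 0.0217) and not with all arrays (adjusted p = 0.329). With an estimated correlation the adjusted p of the fits that passed was 0.0657 and 0.353. Under quantile normalization and the authors' value table with all arrays its median slope at 24 h was above 0, and at 12 h it did not pass (adjusted p = 0.0763 and 0.0624). Under normexp it passed at 24 h too (adjusted p = 0.0292). In the liver and yolk syncytial layer list (69 members) the tyrosine degradation gene hpda (-2.02 ± 0.29, -1.81 ± 0.24), the apolipoprotein gene apoa4a (-1.18 ± 0.44, -1.75 ± 0.22) and rbp4 fell and fah (1.12 ± 0.38, 0.78 ± 0.29) rose. In the cartilage, bone and extracellular matrix list (58 members) col10a1a and fgfbp2b (-2.45 ± 0.31, -2.58 ± 0.30) fell and fn1b rose, and 8 fell and 2 rose without the dim array, and3 (-2.36 ± 0.29) among them, where adjusted p was 3.66e-05 at the preset correlation and adjusted p = 0.353 with an estimated one. Among epidermis and ionocyte genes (62 members) the sodium pump gene atp1a1a.3 (1.92 ± 0.41, 1.59 ± 0.35) and the ionocyte regulator gene foxi3a (1.26 ± 0.29, 1.05 ± 0.24) rose and krt91 fell. This list passed as moving up with all arrays at the preset correlation (adjusted p = 1.28e-05), as under normexp, quantile normalization and the authors' value table, and not with an estimated correlation (adjusted p = 0.34) or without the dim array (adjusted p = 0.631), although it did under quantile normalization without that array (adjusted p = 0.0155). In skeletal muscle the slow-fibre genes smyhc2 (1.85 ± 0.56, 1.24 ± 0.39) and tnnt1 (1.05 ± 0.33, 0.86 ± 0.30) rose in both fits. The skeletal muscle list itself passed as moving down without the dim array at the preset correlation, and slow-fibre genes were not tested as a set.

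Of the lists that follow, neurons and synapses passed at 24 h at the preset correlation in the fit without the dim array, and the others in neither fit. Without the dim array none of the 8 hatching gland genes passed over all genes, 1 of 20 heart muscle genes fell, 1 of 26 glucocorticoid response genes rose, 3 of 27 glia and myelin genes fell, and of 34 cytochrome P450 genes of families 2, 3 and 4 as well as of 39 myeloid genes few passed (2 rose and 2 fell, and 1 rose and 2 fell). Of 40 circadian clock genes 1 fell, aanat2. Of 40 erythroid genes 2 fell, of 40 neurotransmitter receptor genes 1 rose and 1 fell, of 40 immediate early genes 1 rose and 4 fell, egr4 among them (-1.69 ± 0.24), of 42 heat shock genes 1 rose and 3 fell, of 47 glutathione S-transferases and other conjugating enzymes 5 rose and 4 fell, and of 54 pancreas and gut genes 2 rose and 5 fell, the intestinal regulator gene cdx1b among them (-1.27 ± 0.25). Of 65 genes of neurons and synapses 2 rose and 5 fell, and this list moved down without the dim array (adjusted p = 0.0217 at the preset correlation, adjusted p = 0.424 with an estimated one). At 12 h the lists of lens, cartilage, cell cycle and skeletal muscle passed as moving down and those of circadian clock, erythroid, immediate early and inflammation genes as moving up at the preset correlation with all arrays, with adjusted p from 0.0657 to 0.752 with an estimated correlation. Under normexp, quantile normalization and the authors' value table the skeletal muscle list did not pass at 12 h (adjusted p = 0.77, 0.798 and 0.707), and neither did the cell cycle list (adjusted p = 0.897, 0.9 and 0.707). Under normexp the lens and cartilage lists did not pass either (adjusted p = 0.0938 and 0.0986), and the median slope of circadian clock genes was -0.01. For the difference of trends 11 lists passed at the preset correlation with all arrays and 4 without the dim array, for Carbo-Iron 11 and 4, and for 24 h against 12 h controls 11 and 10. With an estimated correlation 0 and 1, 0 and 0, and 3 and 5 of these passed.

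A hypothesis was that PCE slows development, so that genes differing between 24 h and 12 h controls shift the other way under PCE. Without the dim array, 193 of the 242 genes higher in the 24 h controls had negative slopes over the 24 h PCE arrays (79.8%, against 53.2% of all genes), and 38 of the 49 lower genes had positive ones (77.6%). Across 22200 genes the slopes correlated with the control difference at r = -0.279 (rho -0.264, -0.246 and -0.195 within batches 5 and 6, and -0.0782 for the 12 h slopes), where the control arrays of the 2 measures were not shared. Of 100 refits with concentrations shuffled within batch 6 gave r as low, which lies exactly at the bound set in advance. The rule set in advance counted a value at the bound against slower development. A margin of 1 SD of the shuffled values (0.166) was added only after this value had been seen. For slower development it was asked only of a reading against it, and not of a reading in its favour. By that margin slower development and chance cannot be told apart. With array brightness as a covariate r was -0.301 (3 of 100 as low), below the bound of -0.277 from its own refits. The rule set in advance counted this against brightness, while the later margin leaves brightness open too.

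A second pattern examined was a smaller change at 32 mg in the batches with Carbo-Iron. For genes called at the other exposure time without the dim array, the mean change in the called direction was 0.55 in batch 3 and 0.47 in batch 4, and 1.02 in batch 5 and 0.85 in batch 6, ratios of 0.858 and 0.838. Each batch has 1 array at 32 mg, so these values have no spread between arrays, and the smaller change itself is not established. For the same reason compressed signal on these arrays stays open, although the spread of log2 signal in batch 4 was 0.938 of that in batch 3, and in batch 6 0.999 of that in batch 5. Carbo-Iron and the batch cannot be told apart, because every 32 mg array with Carbo-Iron lies in batches 4 and 6.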
